A study of Homo sapiens with 7 samples.

How the data were processed

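Gene expression was measured in human epidermis from 2 donors, as unsorted cells of all layers (total), as integrin β4-positive cells (basal) and as integrin β4-negative cells (suprabasal). Integrin β4, the product of ITGB4, anchors basal keratinocytes to the basement membrane. The 7 arrays gave 6 samples, 2 per group, because the suprabasal cells of donor 2 were hybridised on 2 arrays. The labels do not say whether that repeat started from the same RNA, so both arrays were averaged on the log2 scale and counted as 1 sample. The arrays came as a table of 22277 probe-set intensity values, which the authors had made with Affymetrix MAS5, per the submitters' processing notes. The version of that program, any scaling target and any filter are not given in the sources used here. RNA was labelled with biotin by the manufacturer's standard protocol, per the labels' protocols.

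The deposited intensity values were on a linear scale and had not been brought to a common level. The mean signal after trimming a share of 0.02 from each end ran from 62.1 to 160.5 across arrays, a 2.58-fold range. Each array was therefore scaled to the geometric mean of these values, 96.9. Scaled signals below 0.1 of that mean, 9.69, were set to it (3.28 on the log2 scale), and log2 was taken. Below the floor signals have no order, so where a gene lay at the floor in every sample of a group the fold is given as "at least". List medians include such genes at the floor. The precision of every value is limited by the number of arrays, and p-values of single genes rest on 2 donors per group. Those of gene lists with a preset correlation, described below, take genes as the units. They do not measure the spread between donors.

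The probe annotation gave 1 gene symbol for 19064 probe sets, several for 1043 and none for 2108, beside 62 control probe sets. Through Entrez identifiers, 19052 of the 19064 were matched to current symbols. Because the donors are people, 31 probe sets were left out of every step. A further gene of the layer panel was not analysed here. A probe set was kept when it lay above its array's median (percentile 50) in at least 2 of the 6 samples, which 12616 did, 11102 of them with 1 gene. For each gene the kept probe set with the highest mean was used, which left 7641 genes. Among the genes taken by the naming rule below that passed between suprabasal and basal cells and had another kept probe set, all others had the same sign in 13 of 14, and IL1A was the exception. Against total this held for 1 of 1 such gene in basal and 4 of 4 in suprabasal cells.

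Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on the mean level), two-sided, with all 3 groups in one fit, which left 3 residual and 6.40 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 7641 genes of a comparison, with a threshold of 0.05. Donor was not in this fit. The labels have a donor field, which is the same for same-numbered samples of all groups and so pairs them, and the fit with donor as a block was run as an alternative. Over genes, the deviations of paired samples from their group means correlated at 0.10 (basal and suprabasal), 0.21 (basal and total) and -0.15 (suprabasal and total). Both comparisons with total use the same 2 total samples and so share their chance values.

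A set of 30 gene lists covering layers, pathways, stress and other skin cell types was fixed before the data were examined, as were the tests, the rule for named genes and all alternative settings but those named with their results. The lists hold 883 different genes, of which 603 were measured, 33 of them in more than 1 list. Lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. The preset form takes its degrees of freedom from the number of genes. The estimated form takes the 3 residual ones of the samples. The mast cell and erythroid list had 1 measured gene and was not tested, which left 29. Named genes were the 12 with the largest fold in each direction between suprabasal and basal among those that passed, had groups that did not overlap and lay above the floor in both samples of a group. Against total, 6 in each direction were taken by the same rule, and where none passed in a direction the 5 largest at an unadjusted p under 0.05 are given as not passing. A fixed layer panel and up to 4 members of each list, by smallest p between suprabasal and basal, could also be named. KRT2, melanocyte list genes named against total, and families of genes sharing a symbol stem, were chosen after their values were seen.

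The scripts were tested on simulated data built on the suprabasal and basal comparison of 7641 genes. With 50 genes changed at each size, 4% were recovered at a log2 change of 1, 46% at 2, 60% at 3 and 86% at 4, with 0 sign errors, and 7 of 105 calls were unchanged genes. Of 100 unchanged lists of 30 genes, 3 had a camera p under 0.05 with the preset correlation and 1 with the estimated one. Genes were simulated independently of each other. The simulation therefore cannot tell how the preset correlation serves lists whose members vary together. The estimated correlation was 0.51 for ribosomal protein genes and 0.67 for T cell genes. The alternatives changed the pairing, the normalization, the floor, the filter, the choice of probe sets, the repeat array, the model of the spread, the groups in the fit and the samples, one at a time except for 1 combined change of filter and floor and 1 block with crossed numbers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome coordinates were used.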

Results

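Human epidermis from 2 donors was profiled on 7 Affymetrix arrays. These gave 2 samples each of total epidermal cells, sorted basal (integrin β4-positive) epidermal cells and sorted suprabasal (integrin β4-negative) epidermal cells. The series asked how gene expression changes as keratinocytes leave the basal layer. The trimmed mean signal of the arrays was 74.5 and 62.1 for total, 83.9 and 100.8 for basal, and 85.6, 160.5 and 149.4 for suprabasal samples, the last pair being repeat arrays of suprabasal replicate 2. Across genes, these repeat arrays correlated at 0.957 on the log2 scale, while arrays of the same fraction from different donors correlated at 0.866 to 0.927. The signal ratio of the ACTB control probe sets at the transcript's 3-prime and 5-prime ends, a sign of RNA or labelling quality, was 3.56 and 2.66 in total, 1.65 and 1.63 in basal, and 2.38, 1.90 and 1.80 in suprabasal arrays. For GAPDH this ratio lay between 0.90 and 1.36 on the 7 arrays. Values below are log2 differences of scaled signal ± the model's standard error with n = 2 per group, and adjusted p-values are from limma.

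Suprabasal cells were compared with basal cells to find what separates the layers. ITGB4, which encodes the antigen used for sorting, was 33.1-fold lower in suprabasal cells (-5.05 ± 0.35, adjusted p = 0.000154). This checks the labels and is not a finding. Genes of basal keratinocytes and of their attachment to the basement membrane were among the 12 largest falls. KRT15, a keratin of basal cells, fell 149-fold (-7.22 ± 0.47, adjusted p = 0.000154), and LAMB3, a laminin chain of the basement membrane, fell 22.1-fold (-4.47 ± 0.43, adjusted p = 0.00151). Over all alternative settings the KRT15 difference ran from -8.02 to -6.41. CDH3, the gene of P-cadherin, lay at the floor in both suprabasal samples and was at least 27.5-fold lower (adjusted p = 0.00161). In the opposite direction, ARG1, the arginase that splits arginine into ornithine and urea, rose 11.2-fold (3.49 ± 0.38, adjusted p = 0.00294), and CCL20, a chemokine, rose 13.1-fold (3.71 ± 0.51, adjusted p = 0.00772). SCEL, which encodes the cornified envelope precursor sciellin, rose 7.76-fold (2.96 ± 0.39, adjusted p = 0.00686).

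Among the 12 genes with the largest falls, ASS1, the argininosuccinate synthase of arginine synthesis, had a log2 difference of -5.89 ± 0.41. The calcium-binding protein gene S100A2 was at -5.86 ± 0.64 (-6.93 to -4.80 over the alternative settings). The interferon-induced IFITM3 was at -5.71 ± 0.78 (-6.90 to -4.51 over these settings). PAMR1 lay at -5.12 ± 0.33, the matricellular genes SPARC and THBS2 at -4.87 ± 0.34 and -4.43 ± 0.31, the Notch ligand gene JAG2 at -4.32 ± 0.35 and the tensin gene TNS3 at -4.23 ± 0.40. Their adjusted p-values ran from 0.000154 to 0.00772. The other large rises included HSD11B1, which regenerates cortisol (3.25 ± 0.62, adjusted p = 0.0283), EREG, a ligand of the EGF receptor (3.26 ± 0.70, adjusted p = 0.0397), and KRT23, which was 6.96-fold higher (adjusted p = 0.0154). EREG ranged from 2.10 to 4.41 over the alternative settings. GTF2F2, TTC1, UNC93A and AKTIP rose by 3.03, 3.01, 2.93 and 2.89. AKR1C3, at the floor in both basal samples, was at least 10.7-fold higher (adjusted p = 0.0404). IL1A was also at least 10.7-fold higher (adjusted p = 0.0192), but its other kept probe set was at -0.28, so its direction is not settled. When 1 of the 6 samples was left out in turn, 11 of these 24 genes passed every time. These were KRT15, ASS1, PAMR1, ITGB4, SPARC, CDH3, LAMB3, THBS2, JAG2, TNS3 and ARG1. Without suprabasal replicate 1, or without basal replicate 2, 1 of the 12 higher genes passed, with adjusted p-values of the 12 up to 0.359 and 0.222. Without suprabasal replicate 2 it was 8, and without basal replicate 1 it was 10, with p-values up to 0.123 and 0.0997. Of the 12 lower genes, S100A2 and IFITM3 did not pass without basal replicate 2 (0.0575 and 0.0767).

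The keratins and cornified envelope genes of the layer panel moved less evenly. KRT5 and KRT14, the main keratin pair of basal cells, fell 14.6-fold and 16.03-fold (adjusted p = 0.0256 and 0.0341). Their mean log2 signal was 12.93 ± 0.03 and 13.08 ± 0.02 in basal cells (SD, n = 2). In suprabasal cells it was 9.06 ± 2.00 and 9.07 ± 2.31, so the 2 suprabasal samples stood far apart. As deposited, KRT5 was at 177 in suprabasal replicate 1, and at 1653 and 3138 on the repeat arrays of replicate 2. For KRT14 these signals were 153, and 2242 and 3190. In basal cells KRT5 and KRT14 were as bright as KRT1 and KRT10, where signals rose little with array brightness. The size of these folds is therefore uncertain. KRT5 did not pass without basal replicate 1 (0.0858) or basal replicate 2 (0.175), nor KRT14 without these (0.0968 and 0.201) or without suprabasal replicate 1 (0.0528). Without a trend in the spread model neither passed (0.0749 and 0.0891). KRT1 and KRT10, the main keratin pair of suprabasal cells, differed by -0.08 ± 0.32 and -0.08 ± 0.33 (adjusted p = 0.891 and 0.885). As deposited, KRT1 signals lay between 7060 and 9805 and KRT10 signals between 5892 and 9348 on arrays whose trimmed means spanned 2.58-fold. Before scaling, both were higher in suprabasal than in basal cells of each replicate. KRT1 was at 7974 against 7462 in replicate 1, and at 9805 and 9650 against 7402 in replicate 2. For KRT10 these signals were 7374 against 5928, and 9348 and 9159 against 8263. The suprabasal arrays of replicate 2 were scaled by 0.604 and 0.649, so the differences of -0.08 depend on the scaling. Differences of the envelope genes IVL (1.54 ± 0.57, adjusted p = 0.133), FLG (1.19 ± 0.58, adjusted p = 0.221) and LORICRIN (0.42 ± 0.72, adjusted p = 0.731) did not pass.

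**Figure D1:**
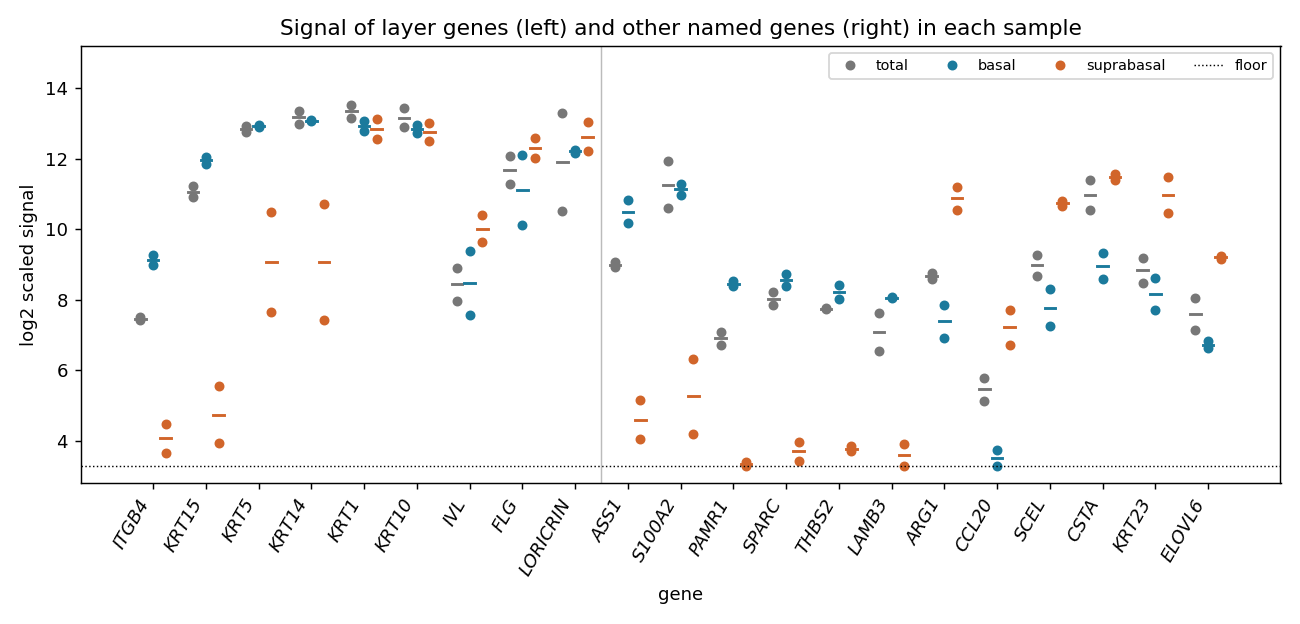
Log2 scaled signal (vertical axis) of layer genes and other named genes (horizontal axis) in total, basal and suprabasal samples; each point is 1 of the 2 samples of a group, each bar the group mean, and the dotted line the floor of 3.28. KRT15 averages 11.96 in basal and 4.74 in suprabasal samples, whereas KRT1 and KRT10 overlap between these groups.

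Basal adhesion genes, matrix genes, cell cycle genes, growth factor genes and interferon-response genes were the lists that shifted down. Of 21 measured basal adhesion genes, 10 fell and 0 rose (18 and 0 when adjusted over the list alone). Their median was -2.14 (camera adjusted p = 4.50e-10, adjusted p = 0.377 with an estimated correlation). COL7A1, the collagen of anchoring fibrils, was at -3.52 ± 0.38. Of 20 extracellular matrix genes, 6 fell and 0 rose (12 and 1 adjusted over the list alone), with a median of -2.03 (adjusted p = 6.75e-06, adjusted p = 0.377 with an estimated correlation). POSTN was at -4.11 ± 0.49 and COL6A1 at -2.45 ± 0.31. Of 42 cell cycle genes, 8 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -1.28 (adjusted p = 2.04e-07, adjusted p = 0.592 with an estimated correlation). The replication helicase genes MCM2 and MCM5 were at -2.37 ± 0.41 and -2.58 ± 0.51, and UBE2C at -1.61 ± 0.32. Of 39 growth factor, ligand and receptor genes, 6 fell and 1, EREG, rose (11 and 1 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.0483, adjusted p = 0.592 with an estimated correlation). DKK3, IGFBP3 and WNT4 were at -4.18 ± 0.53, -3.50 ± 0.35 and -3.25 ± 0.40. Of 33 interferon-response genes, 2 fell, IFITM3 and IFITM2 (-3.57 ± 0.62), and 0 rose (7 and 0 adjusted over the list alone), with a median of -1.14 (adjusted p = 0.00366, adjusted p = 0.6999 with an estimated correlation). The interferon shift did not pass without basal replicate 1 (0.289). The growth factor shift did not pass without basal replicate 1 (0.117), basal replicate 2 (0.0543) or suprabasal replicate 2 (0.0535).

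The lists of cornified envelope genes, barrier lipid genes, proteases with their inhibitors, and cholesterol synthesis genes shifted up. Of 22 cornified envelope and granular genes, 2 rose, SCEL and the protease inhibitor gene CSTA (2.51 ± 0.38), and 0 fell (9 and 0 adjusted over the list alone). Their median was 1.14 (adjusted p = 3.22e-05, adjusted p = 0.592 with an estimated correlation). Of 31 barrier lipid genes, 5 rose and 0 fell (10 and 2 adjusted over the list alone), with a median of 0.54 (adjusted p = 0.00126, adjusted p = 0.592 with an estimated correlation). These included the fatty acid elongases ELOVL6 (2.48 ± 0.36) and ELOVL4 (2.19 ± 0.41), the lipoxygenase ALOX12B (1.71 ± 0.32) and the fatty acid binding protein FABP5 (2.00 ± 0.42). Of 27 protease and inhibitor genes, 2 rose, CSTA and SERPINB7 (1.83 ± 0.33), both inhibitor genes, and 0 fell (10 and 1 adjusted over the list alone), with a median of 0.39 (adjusted p = 0.00784, adjusted p = 0.592 with an estimated correlation). Of 17 cholesterol synthesis genes, 2 rose, INSIG1 (2.26 ± 0.38) and MSMO1 (1.63 ± 0.36), and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.0262, adjusted p = 0.592 with an estimated correlation). INSIG1 is known to restrain this pathway. The cholesterol shift did not pass under quantile normalization (0.0953) or without basal replicate 1 (0.0569). MSMO1 did not pass under quantile normalization either (0.0518).

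In 4 more lists the shift was upward, with few single genes past the threshold. Of 20 heat shock genes 0 passed limma's test over all genes (3 higher and 1 lower adjusted over the list alone, 7 higher and 1 lower at an unadjusted p under 0.05), with a median of 0.69 (adjusted p = 0.00317, adjusted p = 0.592 with an estimated correlation), and without basal replicate 2 the shift did not pass (0.0652). Of 52 ribosomal protein genes 0 passed (0 adjusted over the list alone, 7 unadjusted), with a median of 0.31 (adjusted p = 0.00366, adjusted p = 0.6999 with an estimated correlation), and without basal replicate 1 the shift did not pass (0.449). Of 61 oxidative phosphorylation genes, NDUFB3 rose (1.52 ± 0.31) and UQCRC1 fell (-1.71 ± 0.32), 1 each also adjusted over the list alone, with a median of 0.27 (adjusted p = 0.0303, adjusted p = 0.751 with an estimated correlation). This shift did not pass under quantile normalization (0.351), without basal replicate 1 (0.968) or without suprabasal replicate 2 (0.307). The ACTB end ratio also differed between these fractions, at 1.65 and 1.63 in basal and 1.80 to 2.38 in suprabasal arrays. Of 15 spinous and early differentiation genes 1 rose, FABP5, and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0483, adjusted p = 0.631 with an estimated correlation). With donor as a block (0.0545), under quantile normalization (0.129), and without basal replicate 1 (0.0736), basal replicate 2 (0.0929) or suprabasal replicate 1 (0.138) it did not pass.

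Lists of markers of other skin cells did not pass camera between the sorted fractions. Medians were -0.81 for 12 melanocyte genes (adjusted p = 0.247), 0.67 for 16 Langerhans and dendritic cell genes (0.0653), -0.16 for 9 T cell genes (0.621), -0.39 for 2 Merkel cell genes (0.506), -0.13 for 5 fibroblast genes (0.317) and -1.08 for 3 endothelial and mural cell genes (0.136). Without suprabasal replicate 1 the Langerhans list passed as higher (6.93e-09), and without suprabasal replicate 2 the endothelial and mural list passed as lower (0.0319). In the melanocyte list QPCT rose (1.85 ± 0.38, adjusted p = 0.0365), and in the other 5 lists 0 genes passed. Adjusted over the list alone, QPCT, 2 fibroblast genes, 1 endothelial or mural gene and 1 Merkel cell gene passed, the last 4 lower. HBB, the measured gene of the mast cell and erythroid list, differed by 0.84 ± 0.34 (adjusted p = 0.162).

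The remaining lists did not pass either. Their medians were -0.04 for 15 desmosome genes (adjusted p = 0.727), 0.16 for 12 junction genes (0.0653), 0.12 for 36 transcription factors of differentiation (0.317), 0.04 for 28 immediate early and dissociation genes (0.411), and -0.53 for 13 Notch pathway genes (0.411). They were -0.69 for 20 glycolysis genes (0.110), -0.08 for 29 lysosome genes (0.773), -1.31 for 7 simple and appendage keratins (0.0956), 0.13 for 18 wound keratin, S100 and cytokine genes (0.272) and -0.39 for 11 housekeeping genes (0.287). Single genes that passed in them were CCN1 (-2.91 ± 0.32), JAG2, the glycolytic PKM (-1.53 ± 0.32) and ENO1 (-1.43 ± 0.31), and the hair keratin KRT31 (-3.98 ± 0.48), which fell, and KRT23 and CCL20, which rose, beside S100A2 and IL1A, whose direction is not settled (-0.28 in its other kept probe set). Adjusted over the list alone, the numbers higher and lower were 1 and 0 for junctions, 0 and 1 for immediate early genes, 1 and 1 for Notch, 0 and 5 for glycolysis, 2 and 1 for lysosome, 1 and 3 for simple and appendage keratins, 3 and 2 for wound genes, and 0 and 0 for the others. Median and mean lay below 0 while camera, which compares a list with all other genes, pointed up for desmosome (mean -0.07) and lysosome (mean -0.02), and the T cell median of -0.16 stood against a mean of 0.25. Glycolysis passed under quantile normalization (0.0282), simple and appendage keratins without suprabasal replicate 1 (0.0258), and junctions without suprabasal replicate 2 (0.0244). Beside the 24 genes with the largest folds, 29 panel and list genes named above or in their groups passed. Of these, CCN1 and IGFBP3 passed whichever sample was left out. Without basal replicate 2, 27 of the 29 did not pass, without suprabasal replicate 1 it was 23, without basal replicate 1 it was 17 and without suprabasal replicate 2 it was 11, with adjusted p-values up to 0.239, 0.319, 0.124 and 0.119.

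Over all 7641 genes, 128 were higher and 154 lower in suprabasal than in basal cells, and all 282 had groups that did not overlap and differed at least 2-fold. At an unadjusted p under 0.05 there were 2033 genes, where chance gives 382. Groups did not overlap for 62.0% of all genes, against 33.3% by chance. With donor as a block 209 were higher and 266 lower, and with arrays centred on their medians 267 and 157, so the share of higher genes among calls was 45.4% with trimmed-mean scaling and 63.0% with median centring. The median difference of all genes moved from -0.17 to -0.04 with median centring and to -0.06 with quantile normalization. Without basal replicate 2, 1 gene was higher and 13 lower, without suprabasal replicate 1, 5 and 26, without basal replicate 1, 53 and 40, without suprabasal replicate 2, 40 and 104, and without total replicate 1 or 2, 241 and 280 or 247 and 290.

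**Figure D2:**
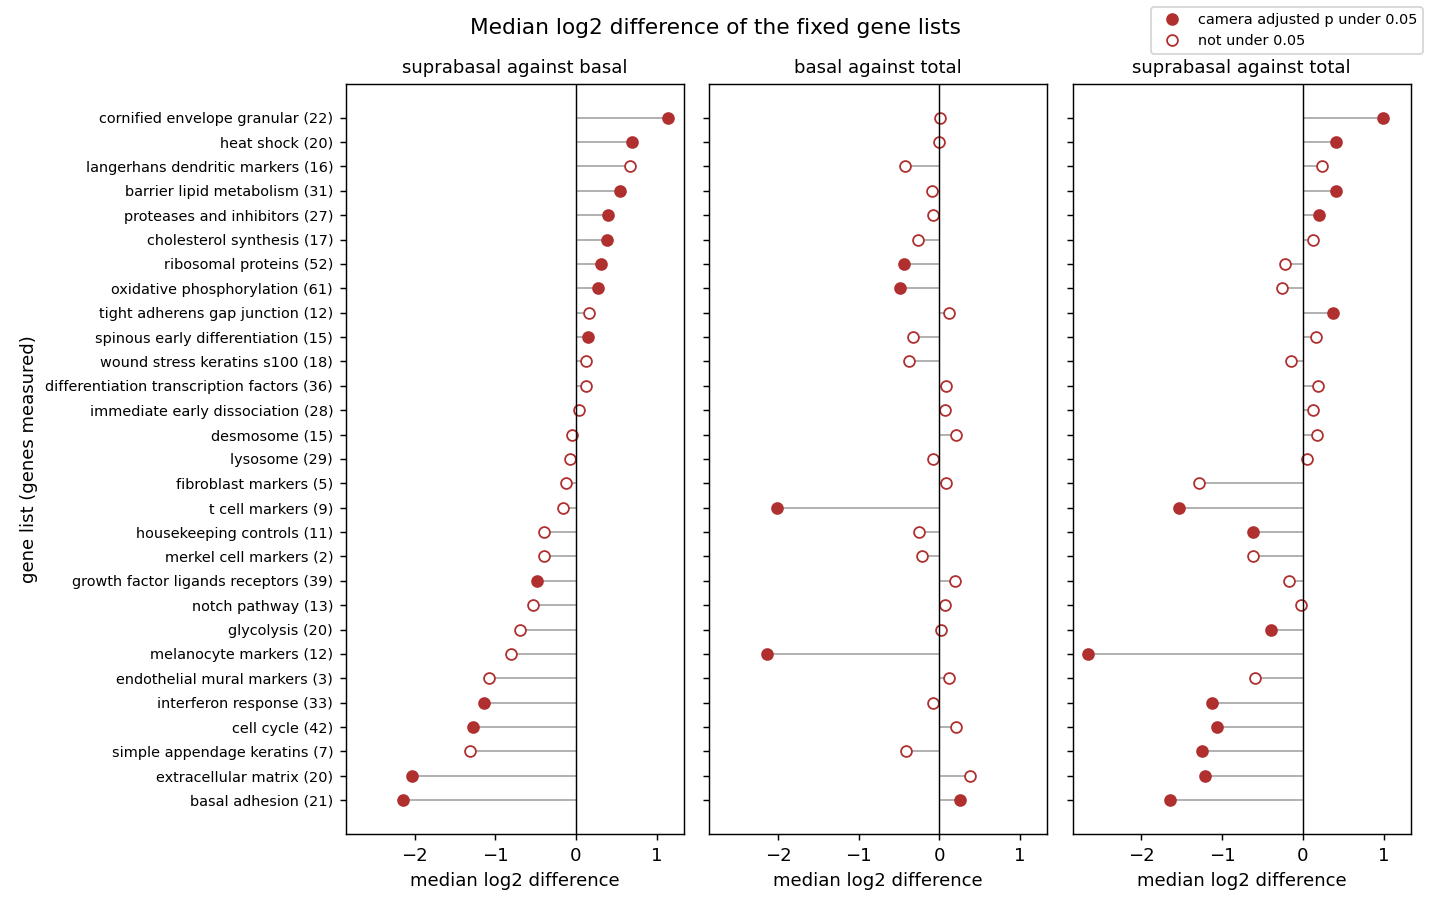
Median log2 difference (horizontal axes) of 29 gene lists (vertical axis, with the number of genes measured) in the 3 comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation, open points do not. Basal adhesion lies at -2.14 and cornified envelope genes at 1.14 in suprabasal against basal cells, and melanocyte markers lie at -2.14 and -2.66 against total.

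Basal cells were compared with total epidermis to see how the sorted fraction departs from the tissue. Melanocyte and T cell markers were lower in the basal fraction as lists, and so was HBB, a haemoglobin gene. HBB fell 8.72-fold (-3.12 ± 0.34, adjusted p = 0.0441). All 12 melanocyte genes had a negative sign, with a median of -2.14 (adjusted p = 1.34e-10, adjusted p = 0.961 with an estimated correlation). Of them 0 passed limma's test over all genes, and 10 were lower adjusted over the list alone and at an unadjusted p under 0.05. TYRP1, a melanin synthesis enzyme, was at -3.48 ± 0.57 and GPM6B at -3.43 ± 0.70 (adjusted p = 0.227 and 0.395). Of 9 T cell genes 8 had a negative sign and 0 passed (0 adjusted over the list alone, 3 unadjusted), with a median of -2.01 (adjusted p = 0.000513, adjusted p = 0.961 with an estimated correlation), and without total replicate 1 the shift did not pass (0.151). Of 21 basal adhesion genes 18 had a positive sign and 0 passed (1 higher adjusted over the list alone, 4 unadjusted). Their median was 0.26 (adjusted p = 0.0210, adjusted p = 0.961 with an estimated correlation). This shift did not pass without basal replicate 1 (0.0587), basal replicate 2 (0.0541) or total replicate 2 (0.237).

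Ribosomal protein genes (52, median -0.44, adjusted p = 4.83e-07) and oxidative phosphorylation genes (61, median -0.49, adjusted p = 2.15e-06) were also lower as lists in basal cells than in total epidermis, both with an adjusted p = 0.961 with an estimated correlation. Of these genes 0 passed over all genes, 13 and 18 had an unadjusted p under 0.05, 3 of the 18 being higher, and 1 ribosomal gene was lower adjusted over the list alone. The ACTB end ratio differed in the same comparison, at 1.65 and 1.63 in basal and 3.56 and 2.66 in total arrays. Without basal replicate 1 neither list passed (0.0934 and 0.197), and without total replicate 1 oxidative phosphorylation did not (0.0688). The other 24 lists did not pass. For wound keratin, S100 and cytokine genes the median was -0.38 (adjusted p = 0.0796, and 0.0316 with donor as a block). The Langerhans and dendritic median was -0.43 (adjusted p = 0.2001). Median, mean and camera differed in sign for cornified envelope genes (median 0.01, mean -0.03, camera down), fibroblast genes (0.08, -0.37, down) and simple and appendage keratins (-0.41, 0.02, up). Leaving out 1 sample brought 6 other lists past the threshold. Cell cycle genes passed as higher without total replicate 1 (2.13e-05) and basal replicate 2 (0.0208), and matrix genes without total replicate 1 (0.0494) and basal replicate 1 (0.0384). Spinous genes passed as lower without total replicate 1 (0.00283), Langerhans genes without either suprabasal replicate (0.0181), and wound genes without total replicate 2 (0.000275), basal replicate 1 (0.0384) or either suprabasal replicate (0.0418). Interferon-response genes passed as lower without total replicate 2 (0.00140) and basal replicate 1 (0.0312) but as higher without total replicate 1 (0.000515) and basal replicate 2 (0.0220).

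ITGB4 differed by 1.66 ± 0.35 between basal and total cells (adjusted p = 0.409), KRT5 by 0.09 ± 0.71, KRT14 by -0.09 ± 0.81, KRT1 by -0.41 ± 0.32, KRT10 by -0.32 ± 0.33, IVL by 0.03 ± 0.57, FLG by -0.55 ± 0.58 and LORICRIN by 0.29 ± 0.72, and 0 of these passed. In limma 0 genes were higher and 1, HBB, was lower, while 837 had an unadjusted p under 0.05, where chance gives 382. The largest positive differences at that level, none of which passed, were those of PLEC (2.98 ± 0.59), the collagen chaperone gene SERPINH1 (2.88 ± 0.68), SLC6A2 (2.75 ± 0.87), RRS1 (2.68 ± 0.38) and RAB40C (2.57 ± 0.77). HBB did not pass with donor as a block (0.0893) or without any 1 of the 6 samples. Its adjusted p was then 0.222 and 0.0963 without total replicates 1 and 2, 0.132 and 0.361 without basal replicates 1 and 2, and 0.0678 and 0.0642 without suprabasal replicates 1 and 2.

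Suprabasal cells were compared with total epidermis in the same way, against the same 2 total samples. Among the 6 largest falls were KRT15 at -6.33 ± 0.47 (adjusted p = 0.000832), S100A2 at -6.00 ± 0.64 (0.00454) and ASS1 at -4.39 ± 0.41 (0.00208). ITGB4, the sorting antigen, lay at -3.39 ± 0.35 (0.00403). CDH3 was at least 25.4-fold lower (adjusted p = 0.00331). IFITM3 (-4.68 ± 0.78) and the melanocyte list gene GPM6B (-4.53 ± 0.70) fell too (adjusted p = 0.0404 and 0.0313). ARG1 rose 4.61-fold (2.20 ± 0.38, adjusted p = 0.0428), and HOMER2, TUT7, PTPN13, SLK and the kinesin gene KIF5B rose by 1.99, 1.93, 1.89, 1.89 and 1.83 (adjusted p = 0.0375 to 0.0428). Under quantile normalization IFITM3, TUT7 and KIF5B (0.0517 each), ARG1 (0.0716), SLK (0.0736) and PTPN13 (0.0775) did not pass. HBB fell by 2.29 (adjusted p = 0.0294). KRT5 (-3.77 ± 0.71, adjusted p = 0.0611) and KRT14 (-4.10 ± 0.81, adjusted p = 0.0688) passed with donor as a block (0.0427 and 0.0434). KRT1 (-0.49 ± 0.32), KRT10 (-0.40 ± 0.33), IVL (1.58 ± 0.57), FLG (0.64 ± 0.58) and LORICRIN (0.71 ± 0.72) did not pass.

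As lists, 9 were lower and 5 higher in suprabasal cells than in total epidermis. The ACTB end ratio differed here too, at 1.80 to 2.38 in suprabasal and 3.56 and 2.66 in total arrays. The lowest was that of melanocyte markers, where 12 of 12 signs were negative and GPM6B, TYRP1 (-3.61 ± 0.57) and MITF (-2.37 ± 0.40) fell (11 lower adjusted over the list alone). The list median was -2.66 (adjusted p = 1.14e-10, adjusted p = 0.433 with an estimated correlation). Basal adhesion had a median of -1.64 (4 of 21 fell, 15 adjusted over the list alone, adjusted p = 1.14e-10, adjusted p = 0.358 with an estimated correlation), and extracellular matrix -1.21 (3 of 20 fell, 9 lower and 1 higher adjusted over the list alone, adjusted p = 4.66e-06, adjusted p = 0.358 with an estimated correlation). Cell cycle genes had a median of -1.06 (0 of 42 passed, 12 lower adjusted over the list alone, 23 unadjusted, adjusted p = 2.16e-07, adjusted p = 0.433 with an estimated correlation). Higher were cornified envelope genes (median 0.99, 0 of 22 passed, 8 higher adjusted over the list alone, 11 unadjusted, adjusted p = 1.97e-07), barrier lipid genes (0.41, 0 of 31 passed, 6 higher and 1 lower adjusted over the list alone, 9 and 2 unadjusted, adjusted p = 0.000820), heat shock genes (0.41, 0 of 20, 0 adjusted over the list alone, 5 unadjusted, adjusted p = 0.000898), and proteases and inhibitors (0.20, 0 of 27, 4 higher adjusted over the list alone, 7 higher and 1 lower unadjusted, adjusted p = 0.00882). With an estimated correlation the adjusted p = 0.433 for each of these 4. Proteases did not pass without total replicate 2 (0.0704).

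The other lists that passed against total each lost the call in at least 1 setting that left out a sample. Interferon-response genes had a median of -1.13 (1 of 33 fell, 3 adjusted over the list alone, adjusted p = 6.29e-05, adjusted p = 0.530 with an estimated correlation, and 0.407 without total replicate 1). T cell genes had a median of -1.54 (0 of 9, 0 adjusted over the list alone, 3 unadjusted, adjusted p = 0.0130, adjusted p = 0.530 with an estimated correlation), which did not pass without total replicate 1 (0.571) or suprabasal replicate 1 (0.104). Junction genes were at 0.38 (0 of 12, 0 adjusted over the list alone, 4 unadjusted, adjusted p = 0.0152, adjusted p = 0.468 with an estimated correlation, 0.333 without total replicate 1 and 0.119 without suprabasal replicate 1). Housekeeping genes lay at -0.61 (0 of 11, 0 adjusted over the list alone, 2 unadjusted, adjusted p = 0.0211, adjusted p = 0.433 with an estimated correlation, 0.183 without total replicate 1 and 0.0582 without suprabasal replicate 1). Simple and appendage keratins lay at -1.26 (0 of 7, 1 higher and 4 lower adjusted over the list alone and unadjusted, adjusted p = 0.0286, adjusted p = 0.433 with an estimated correlation, 0.265 without total replicate 1 and 0.190 without suprabasal replicate 2). Glycolysis genes lay at -0.40 (0 of 20, 1 lower adjusted over the list alone, 1 higher and 5 lower unadjusted, adjusted p = 0.0483, adjusted p = 0.433 with an estimated correlation). Glycolysis did not pass with donor as a block (0.0575), without total replicate 1 (0.249), without suprabasal replicate 1 (0.211) or without either basal replicate (0.0578). The Langerhans and dendritic median was 0.24 (adjusted p = 0.398), but this list passed as higher without suprabasal replicate 1 (4.35e-09) and as lower without suprabasal replicate 2 (0.00369). Other lists that passed with 1 sample left out were desmosome (0.0408), immediate early (0.00442), spinous (0.0143), ribosomal (0.0109), oxidative phosphorylation (0.000213) and differentiation transcription factor genes (0.00277) without total replicate 2, the last 2 (0.0193) and endothelial and mural genes (0.0356) without suprabasal replicate 2, and growth factor genes (0.0215) without total replicate 1. Under quantile normalization growth factor (0.0308) and oxidative phosphorylation genes (0.00347) passed. Wound keratin, S100 and cytokine genes had a median of -0.15 and a mean of -0.51 where camera pointed up, and lysosome genes a median of 0.05 and a mean of -0.03.

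Over all genes, 7 were higher and 34 lower in suprabasal cells than in total epidermis, 16 and 48 with donor as a block, while 1080 had an unadjusted p under 0.05. Quantile normalization gave 1 higher and 24 lower, and leaving out 1 sample gave 0 to 20 higher and 9 to 73 lower, with 0 and 9 without suprabasal replicate 1, 0 and 17 or 0 and 16 without basal replicate 1 or 2, 3 and 18 without total replicate 1, 1 and 26 without suprabasal replicate 2, and 20 and 73 without total replicate 2. Of the 12 named genes, KRT15, S100A2, CDH3 and ASS1 passed whichever sample was left out. With 1 sample left out, the 6 higher ones passed in no fit but that without total replicate 2, where 4 did. In that setting the highest adjusted p was 0.0659, and without suprabasal replicate 1 it was 0.441. Without that sample GPM6B and IFITM3 had an adjusted p of 0.257. Neither passed without total replicate 1 (0.121 and 0.129), without basal replicate 1 (0.0705 and 0.0711) or without basal replicate 2 (0.0752 and 0.0770), and GPM6B did not pass without suprabasal replicate 2 (0.0532).

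**Figure D3:**
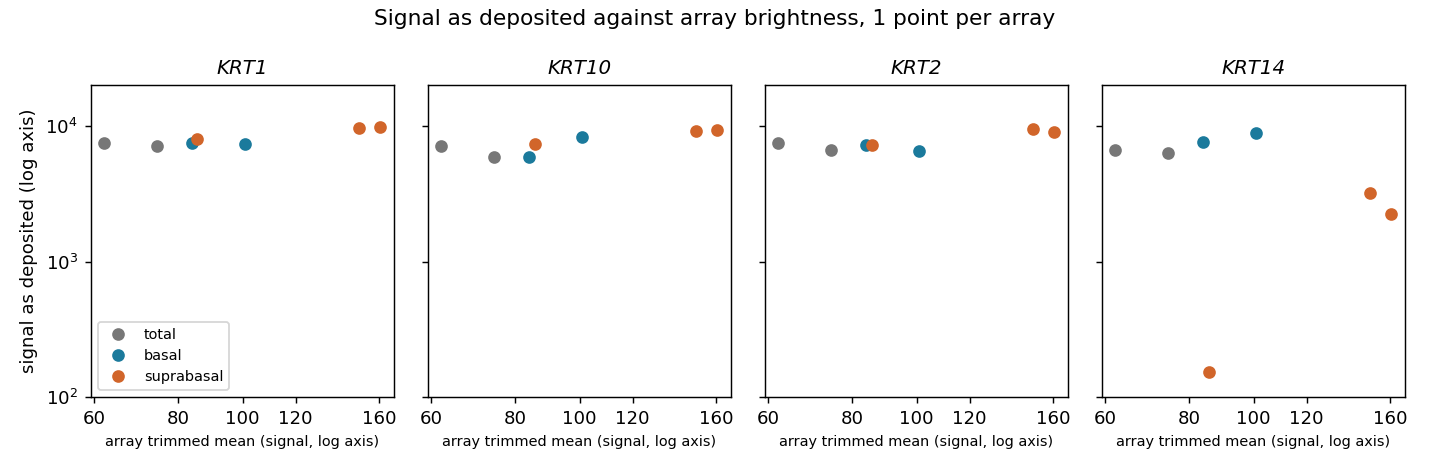
Signal as deposited (vertical axis, log scale) of KRT1, KRT10, KRT2 and KRT14 against the trimmed mean signal of the array (horizontal axis, log scale); each point is 1 of the 7 arrays, coloured by group. KRT1 stays between 7060 and 9805 on all 7 arrays, while KRT14 ranges from 153 to 8916.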

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

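With 2 samples per group, whether a sample stood apart from its group was not tested. Among 1476 kept probe sets that the annotation does not tie to 1 gene, which no comparison above uses, 1 was higher and 6 were lower in suprabasal than in basal cells at a limma adjusted p under 0.05. No explanation of these was tested.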

How the results depend on the processing

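The combined change of filter and floor and the crossed numbers were chosen after the data were seen, and all other alternatives before. With 1 sample left in a group, limma assumes that it varies like the others. Between suprabasal and basal cells, leaving out 1 sample gave 1 to 247 higher and 13 to 290 lower genes. Donor as a block gave 209 and 266, median centring 267 higher, a spread model without trend 12 and 58, and a fit of only these 2 groups 260 and 291. Without the filter 0 passed in every comparison. There 569 of 11939 genes had equal values within every group, the prior degrees of freedom dropped to 1.07 from 6.40, and the smallest adjusted p between suprabasal and basal was 0.0657. With an added offset in place of the floor and no filter, the numbers were 46 and 62, with 106 of these 108 calls shared with the 282. For basal against total the 1 lower gene fell to 0 with the donor block, the floor at 0.2, the first repeat array only, no trend, only 2 groups, no filter with or without the offset, and without any 1 sample. For suprabasal against total, higher genes numbered 16 with the donor block, 1 with quantile normalization, 13 with median centring, 3 and 19 with the first or second repeat array, 1 without trend, 0 with only 2 groups, 0 without the filter and with the offset, and 0 to 20 with 1 sample left out. Lower genes numbered 11 without trend, 12 with only 2 groups, 0 without the filter, 11 with the offset and no filter, and 9 to 73 with 1 sample left out. With suprabasal numbers crossed in the block, 23 were higher and 66 lower, against 16 and 48 with the labels' numbers.

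List calls numbered 0 in every comparison with an estimated correlation, against 13, 5 and 14 with the preset one. The smallest adjusted p was then 0.377, 0.961 and 0.358. For matrix genes between suprabasal and basal cells the estimate, 0.0042, lay below the preset 0.01. Even so, camera's unadjusted p went from 6.98e-07 to 0.0137. For a simulated list of 30 changed genes drawn independently it went from 1.84e-20 to 0.00276. With an estimated correlation camera also uses the 3 residual degrees of freedom in place of about the number of genes. A call lost with the estimated correlation is therefore not by itself a sign that list members vary together. With 1 sample left out, the fewest lists past the threshold were 7 between suprabasal and basal (without basal replicate 1) and 9 between suprabasal and total (without total replicate 1). Directions turned in 5 cases where the main or the alternative value passed. Sign changes between values that did not pass were not counted. IL1A went to -0.28 with a floor at 0.04 and without shared-sequence probe sets, both of which select its other probe set. Interferon-response genes passed as higher in basal than total cells without total replicate 1 (0.000515) and without basal replicate 2 (0.0220), with adjusted p-values from 0.000515 to 0.930 over the samples left out. Langerhans genes passed as lower in suprabasal than total cells without suprabasal replicate 2 (0.00369), with values from 4.35e-09 to 0.728. Except where a cause is given here, the cause was not tested. Beyond these and the changes named with the results, the donor block changed no list call, and it kept all 282 and all 41 genes. Over all alternatives and named genes, 2322 of 2671 values between suprabasal and basal kept their side of the threshold, 278 of 291 between basal and total, and 312 of 420 between suprabasal and total. A change of sign counted against a value only where it passed before or after the change. A model with all 7 arrays and sample as a random block could not be fitted and was not run. Signals near the floor limit the folds of dim genes, with 22.6% to 28.1% of gene probe sets at the floor per array.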

Other observations

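The tests here were chosen after the results were seen, except that of the interferon-response list with the preset correlation and that of gene families, which were set before they were run. Gene families were formed after the data were examined, from measured genes that share the letters before the first digit of their symbol. Of 125 families with at least 8 measured genes, 4 passed camera between suprabasal and basal cells with the preset correlation and 0 with the estimated one (adjusted p = 0.978 for each). Collagen genes lay lower, with 15 of 17 signs negative, 4 genes past the threshold and a median of -1.37 (adjusted p = 0.000589), and 9 of the 17 were in the fixed lists. Keratin genes lay lower as a family, with 18 of 21 signs negative, 1 gene higher and 4 lower past the threshold, and a median of -1.11 (adjusted p = 0.0274). The RPL genes of the large ribosomal subunit (25 of 33 positive, 0 past the threshold, median 0.35) and the HSPA heat shock genes (9 of 10 positive, 1 past the threshold, median 0.94) lay higher, both with an adjusted p = 0.0290. Of the keratin, RPL and HSPA genes, 14 of 21, 29 of 33 and 6 of 10 were in the fixed lists, so they mostly repeat lists tested before. Other settings were tried after these results were seen. Directions held under quantile normalization and median centring, but under the first of these keratin (0.0510) and RPL genes (0.0539) did not pass. Collagen genes passed whichever sample was left out (up to 0.00214). Without basal replicate 1 keratin (0.0677) and RPL genes (0.643) did not pass, without basal replicate 2 HSPA genes (0.178) did not, and without suprabasal replicate 2 keratin, RPL (both 0.0633) and HSPA genes (0.133) did not.

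Metallothionein genes, which were in no fixed list and encode metal-binding proteins, had 9 of 9 negative signs, 0 genes past the threshold and a median of -1.27 between suprabasal and basal cells but did not pass (adjusted p = 0.150). They passed with donor as a block (0.0337), without basal replicate 1 (0.00287) and without suprabasal replicate 2 (0.0364), and had an adjusted p of 0.6996 without basal replicate 2. PARP genes likewise had 8 of 8 negative signs and 0 past the threshold, with a median of -0.87 (adjusted p = 0.150, and 0.0267 without basal replicate 2). MCM genes, most of them replication genes, did not pass camera (7 of 8 negative, 3 lower past the threshold, median -1.24, adjusted p = 0.0519). They did not pass with donor as a block either (0.0822), but did under quantile normalization (0.0432) and median centring (0.0358). With 1 sample left out, their median ran from -1.54 (without suprabasal replicate 2) to -0.95 (without suprabasal replicate 1).

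As deposited, KRT1, KRT10 and KRT2 were higher on the suprabasal than on the basal arrays of each replicate. KRT2 in replicate 1 was so by little, at 7204 against 7172. In replicate 2 the suprabasal arrays were brighter as a whole, with trimmed means of 160.5 and 149.4 against 100.8. In scaled signal the 3 keratins did not pass the test between suprabasal and basal cells, at a mean difference of -0.08. A candidate explanation is that probe sets this bright follow the array only weakly. Within fractions, their unscaled log2 signal rose with array brightness at a mean slope of 0.309 (SD 0.0655 over the 3 genes), against a median of 1.05 for genes with a mean log2 signal of 6 to 8, and most of the range in brightness came from the suprabasal arrays. For 54 genes at 12 or more the median slope was 0.714 (quartiles 0.462 to 0.917), well above that of the keratins, while the 3 other genes as bright as these keratins had a median of 0.351, too few to settle it. Within a fraction the arrays differ by donor, apart from the repeat arrays, so these slopes cannot separate array response from donor differences. The same slope was 3.75 for KRT5 and 4.17 for KRT14. It was -0.44 for LORICRIN and -0.23 for FLG, whose signals went down to 1136 and 1167. Against a hard ceiling, a spiked control of bacteriophage P1 reached 13333 with a slope of 0.881. A basal fraction with as many suprabasal cells as the suprabasal one is argued against, since the other 33 spinous and cornified list genes had a median difference of 0.905 (95% bootstrap over genes 0.417 to 1.19, and 0.67 and 0.96 in the 2 replicates). The bootstrap resampled genes and does not measure the spread between donors. The argument rests mainly on cornified envelope genes, whose list median was 1.14, against 0.15 for the whole spinous list. A smaller carry-over, and transcripts already made in integrin β4-positive cells, stay open.

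Melanocyte markers lay lower in both sorted fractions than in total epidermis, although both comparisons share the total samples. Array scaling is argued against, since their medians were -2.27 and -2.54 after quantile normalization, the nearer to 0 being -2.27. An equal loss of melanocytes and Langerhans cells is argued against too. Against total, the Langerhans median lay above the melanocyte median by 1.604 and 1.57 in basal cells of replicates 1 and 2. In suprabasal cells it did so by 2.40 and 3.28, the lowest of all being 1.57. The Langerhans median itself went from -1.29 to 1.62 between replicates in suprabasal cells. This argument needs both lists to be equally specific and equally far above the floor, which was not checked. In basal cells the T cell median, -2.01, lay close to the melanocyte median, -2.14. TYRP1, the brightest of the 12 measured melanocyte genes in total samples, averaged 11.27 in total, 7.79 in basal and 7.66 in suprabasal samples. With each fraction set against the total sample of its own replicate, the melanocyte medians were -2.53 and -1.60 in basal cells. They were -3.69 and -1.66 in suprabasal cells of replicates 1 and 2. These values argue against 1 deviating total sample as the source. Melanocytes lost in preparation, and a deviation shared by both total samples, may account for the lower markers and were not tested. T cell markers were less even. Their medians were -1.96 and -0.89 in basal and -2.97 and 0.11 in suprabasal cells against total, and the list did not pass without total replicate 1 (0.151 and 0.571) or, in suprabasal cells, without suprabasal replicate 1 (0.104).

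The lower interferon-response list in suprabasal cells might rest on IFITM1, IFITM2 and IFITM3 alone. Without them limma's camera gave 0.00873 for the 30 other genes with the preset correlation (unadjusted, median -0.94 against -1.14 for the full list, 27 of 30 negative), which argues against that. With an estimated correlation neither the full list (0.450) nor the 30 genes (0.519) passed, so whether the list shifted at all stays open. The median of the 30 genes was -1.71 in replicate 1 and -0.17 in replicate 2, where all genes had a median of -0.16. Without basal replicate 1 the full list went to a median of -0.44 and did not pass (0.289), while with donor as a block it passed (0.00245).

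A further hypothesis was that total epidermis is a mixture of both sorted fractions. Mixing weights were estimated in each donor from genes chosen in the other as high in 1 fraction. They were 0.541 for basal and 0.366 for suprabasal in replicate 1, from 19 and 76 genes, and 0.518 and 0.439 in replicate 2, from 30 and 60 genes. For these genes the sums, 0.907 (95% bootstrap 0.644 to 1.06) and 0.957 (0.787 to 1.08), lay near the 1 of such a mixture. Genes high in neither fraction had no part in them. The fit of single genes was not tested. Basal minus total differences of the 21 basal adhesion genes had a median of 0.26 and an SD of 0.68. A mixture of the 2 fractions alone is argued against by the melanocyte genes. In total they lay above the higher fraction by a median of 2.38 in replicate 1 and 1.29 in replicate 2, with 12 of 12 positive in each. This restates the lower melanocyte markers described above and is not separate support. The weights are shares of scaled signal and not of cells.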
